A study of Mus musculus with 12 samples.

How the data were processed

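Per the labels, hindbrains of ICR embryos at E16.5 were frozen and sectioned, motor neurons were found by a cresyl violet stain, and subnuclei were cut out by laser. Tissue of 3 embryos was pooled for each sample, and at least 1.5 ng of total RNA was amplified (WT-Ovation Pico), biotin-labelled (FL-Ovation) and hybridised to an Affymetrix array of the mouse 430 design. The labels name 4 subnuclei with 3 samples each and no control group. They number the samples 1 to 3 within each subnucleus and do not say that equal numbers share embryos.

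The deposited values are probe set intensities on a linear scale, as the range of the values shows. The software that summarised probes into probe sets is not given in the sources used here. On every array the mean without the lowest and highest 2% of the 45101 probe sets was 250, so the authors had scaled the arrays to a common trimmed mean. Array medians ran from 34.5 to 45.8 intensity units. A further deposited table held the same 541212 cells, each exactly equal, together with the authors' mean intensity of each subnucleus and the ratio of each pair of means. The ratios were used here only for Etv1.

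Detection calls were not used here. A probe set was kept if it lay above its own array's 40th percentile on at least 3 arrays, that is above 17.9 to 26.1 intensity units. This kept 30073 probe sets. The 64 control probe sets and the 188 probe sets that carry several gene names were left out. Of the remainder, 10196 probe sets carried no gene name in the deposited table, of which 4894 passed the filter and were examined apart. Each gene was represented by its kept probe set of highest mean over all 12 arrays, which gave 15084 genes, and 6130 genes had more than 1 kept probe set. Gene names were the full names of the deposited table, which holds no symbols. Of 688 symbols in the fixed lists 624 were matched by hand to such a name, and 563 were tested. The plan had foreseen symbols in the files. The older name of Slc32a1 was matched only after a first look at the values, and the list of inhibitory neurons was also tested without it. The counts of genes apart from each other subnucleus and the fit of unnamed probe sets were added after the data were seen. Chat was planned as a named gene but carried no name of its own in that table and was not analysed here.

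Values were taken as log2(intensity + 16) and fitted with limma 3.58.1 in R 4.3.3 (lmFit with a mean per subnucleus on all 12 arrays, eBayes with default settings). Contrasts set each subnucleus against the mean of the other 3 and against each of the other subnuclei, and an F test asked for any difference. P-values were adjusted by Benjamini-Hochberg over genes within each contrast, with 0.05 as the threshold. Of 21 pathway and 11 cell type lists, 30 had at least 5 measured genes, and the lists of Hox genes and of glutamatergic neurons were not tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, with the correlation estimated as an alternative and with fry, adjusted over the lists. The results of fry are not printed here, and list calls are described as held or lost by camera alone. The gene lists, the main tests, the filter and the naming rule were fixed before the data were examined.

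Genes were named by rule: in each subnucleus the 10 largest log2 differences in each direction among genes past the threshold whose 3 arrays lay on the same side of the mean of the others, 3 in each direction for each pair, and up to 4 members of each list. Predicted and unnamed transcripts were counted but passed over, and 12 genes were always to be named, of which not all are printed here. The fit was tested on simulated data for dorsolateral tissue against the others, with 200 of 15084 genes changed. Each gene was drawn independently from a normal distribution with its own spread, with no deviating arrays and no other differences among subnuclei. The rates therefore hold for that simpler setting. It recovered 71% of 100 genes changed by 1 log2 unit and 96% of 100 changed by 2, with 14 unchanged genes called. For dorsolateral against intermediate tissue it recovered 50% and 92%, with 7 unchanged genes called.

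Array measures differed somewhat between subnuclei. Array medians were 43.1 to 45.8 in dorsolateral and 34.5 to 39.5 in lateral tissue. Array weights ran from 0.568 on lateral replicate 3 to 1.725 on medial replicate 3. Pearson correlations of log2 values over kept probe sets were 0.966 to 0.978 within subnuclei and 0.944 to 0.969 between them. The mean log2 ratio of 3' to 5' control probe sets of actin and Gapdh ran from 0.794 on dorsolateral replicate 2 to 1.15 on lateral replicate 3. Alternatives were no filter, a stricter filter (60th percentile on at least 6 arrays), quantile normalization, median centring, the mean of a gene's probe sets, trend and robust eBayes settings, array weights, the replicate number as a block, leaving out each array, a pseudocount of 1, pairwise fits on 6 arrays only, and an Xist covariate added after the data were seen.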

Results

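The series profiled gene expression in the facial motor nucleus, the hindbrain group of motor neurons that drives the muscles of the face, in ICR mouse embryos at E16.5. Its motor neurons lie in subnuclei, and 4 of these were sampled: dorsolateral, intermediate, lateral and medial. Tissue of each subnucleus was laser-captured from hindbrain sections. Each of the 12 samples pooled tissue of 3 embryos and was read on 1 Affymetrix array, which gave 3 arrays per subnucleus. Values are array intensities in arbitrary units, every mean ± SD is over the 3 arrays of a subnucleus (n = 3), and 15084 genes were tested. Folds and log2 differences compare a subnucleus with the mean of the other 3 on the log2(intensity + 16) scale, which understates changes of dim genes. The small number of arrays limits the precision. The labels do not say whether any embryo contributed to more than 1 sample, so p-values measure the spread between these pools.

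Genes of cholinergic motor neurons were bright in all captures. Isl1, a homeodomain factor of motor neurons, was at 4073 ± 38.4 in dorsolateral, 4540 ± 260 in intermediate, 4271 ± 639 in lateral and 4219 ± 532 in medial tissue. Its adjusted p for any difference among the subnuclei was 0.883 by limma's F test. None of the 11 measured cholinergic and neurofilament genes passed the test in any subnucleus against the others, adjusted over all genes. Adjusted over the list alone, 1 member was higher in medial and 1 lower in lateral tissue. The vesicular acetylcholine transporter Slc18a3 was at 1818 ± 325, 1473 ± 155, 1494 ± 235 and 1752 ± 597 in dorsolateral, intermediate, lateral and medial tissue. The neurofilament gene Nefl was at 13970 ± 3450, 13110 ± 3010, 13210 ± 2830 and 12910 ± 592 in the same order.

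The pools differed in sex-linked transcripts, although the labels give every sample as male and female. Xist, the RNA that coats the inactive X chromosome, was at 7.5 and 9.6 on medial replicates 2 and 3 and at 1724 on medial replicate 1. It was at 191.5 on dorsolateral replicate 2 and 97.1 on lateral replicate 3, and between 1048 and 2398 on the other arrays. The Y-linked gene Ddx3y was lowest on dorsolateral replicate 1, at 28.4, and highest on medial replicate 3, at 268.8.

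**Figure D1:**
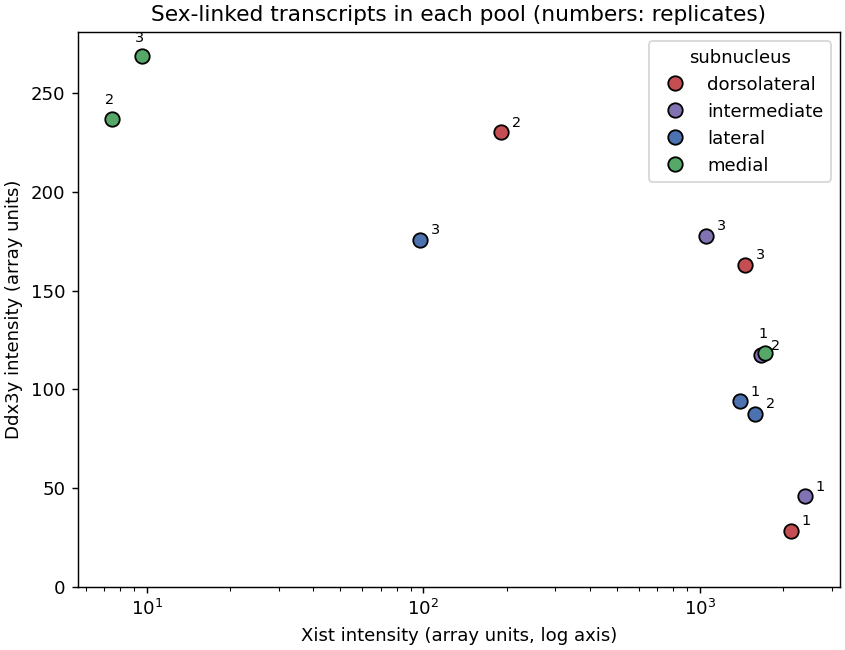
Intensity of the Y-linked gene Ddx3y (vertical axis, array units) against that of Xist (horizontal axis, array units, log scale) on each of the 12 arrays, coloured by subnucleus and numbered by replicate. Medial replicates 2 and 3 sit at the far left with Xist at 7.5 and 9.6, while dorsolateral replicate 1 sits at the lower right with Ddx3y at 28.4.

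The first question was whether the subnuclei differ at all. They did, in 1263 of 15084 genes (8.37%) by limma's F test at an adjusted p of 0.05. Among them were the guidance receptors Epha7 (adjusted p = 1.24e-05), Epha3 (0.000739), Epha4 (0.0114) and Epha5 (0.00484), and their ligand Efna5 (0.00058). Tbx20, a T-box factor of cranial motor neurons, differed too (0.00729). Against the other subnuclei, 438 genes differed in dorsolateral, 361 in intermediate, 1098 in lateral and 398 in medial tissue. A gene high in 1 subnucleus pulls the others down in these comparisons, so the genes apart from each of the other 3 subnuclei in the pairwise tests were also counted, a count chosen after the data were seen. By that count 39 genes were higher and 25 lower in dorsolateral tissue, 51 and 16 in intermediate, 70 and 96 in lateral, and 35 and 13 in medial. With limma's trend and robust settings the F test gave 1926 genes.

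**Figure D2:**
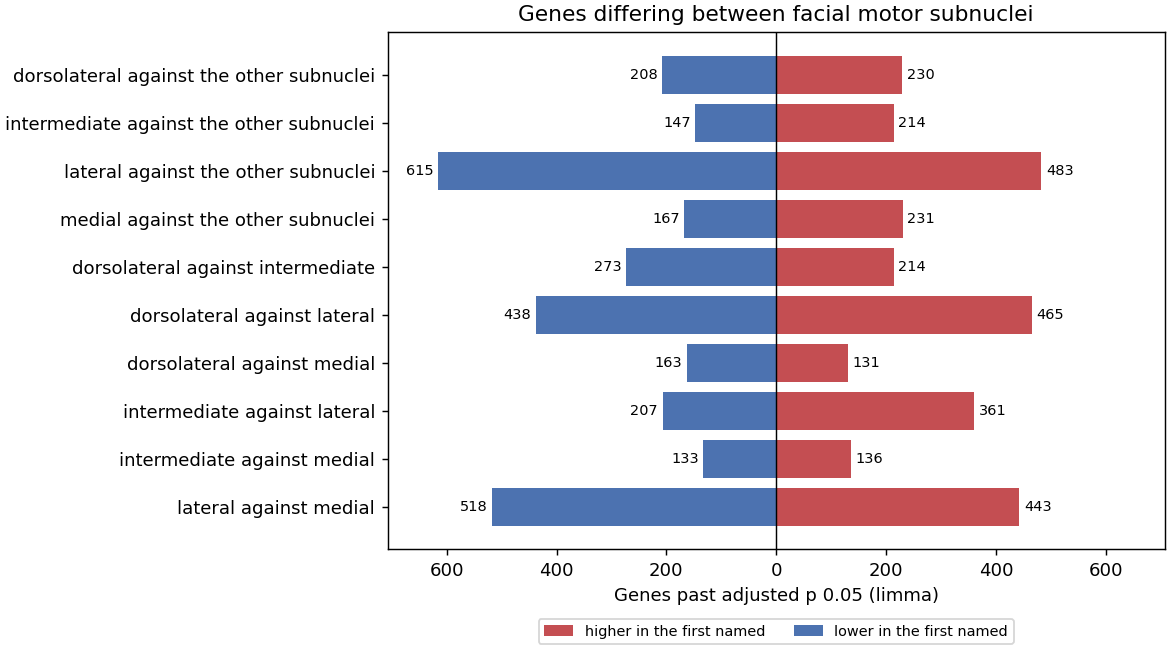
Number of genes past an adjusted p of 0.05 in each comparison (horizontal axis, genes; limma), higher in the first named subnucleus to the right and lower to the left. The lateral subnucleus stands out with 483 genes higher and 615 lower than in the others.

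Etv1, an ETS-domain transcription factor and the gene named in the title of the series, was the gene most raised in the dorsolateral subnucleus. It was at 2929 ± 76.6 in dorsolateral tissue, against 89.6 ± 46.2 in intermediate, 44.4 ± 17.9 in lateral and 139 ± 60 in medial tissue. That was a log2 difference of 4.95 ± 0.258 (SE), or 30.9-fold, with an adjusted p of 9.09e-07 by limma, and all 3 dorsolateral arrays lay above all others. The same contrast was -1.56 in intermediate (adjusted p = 0.00587) and -2.58 in lateral tissue (8.61e-05). In medial tissue it was -0.80 and did not pass (adjusted p = 0.149). The intermediate call was lost without intermediate replicate 1 (-1.40, adjusted p = 0.0527). In the authors' deposited table, the ratio of dorsolateral to intermediate means was 32.7, to lateral means 65.9 and to medial means 21.1. Its relatives behaved otherwise: Etv4 did not pass in any subnucleus, at 66.3 ± 21.2, 99.3 ± 112, 58.5 ± 32.8 and 114 ± 14.7 in dorsolateral, intermediate, lateral and medial tissue. Etv5 was lower in lateral tissue, at 137 ± 36.9 against 247 to 288 elsewhere (log2 difference -0.90, adjusted p = 0.01).

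**Figure D3:**
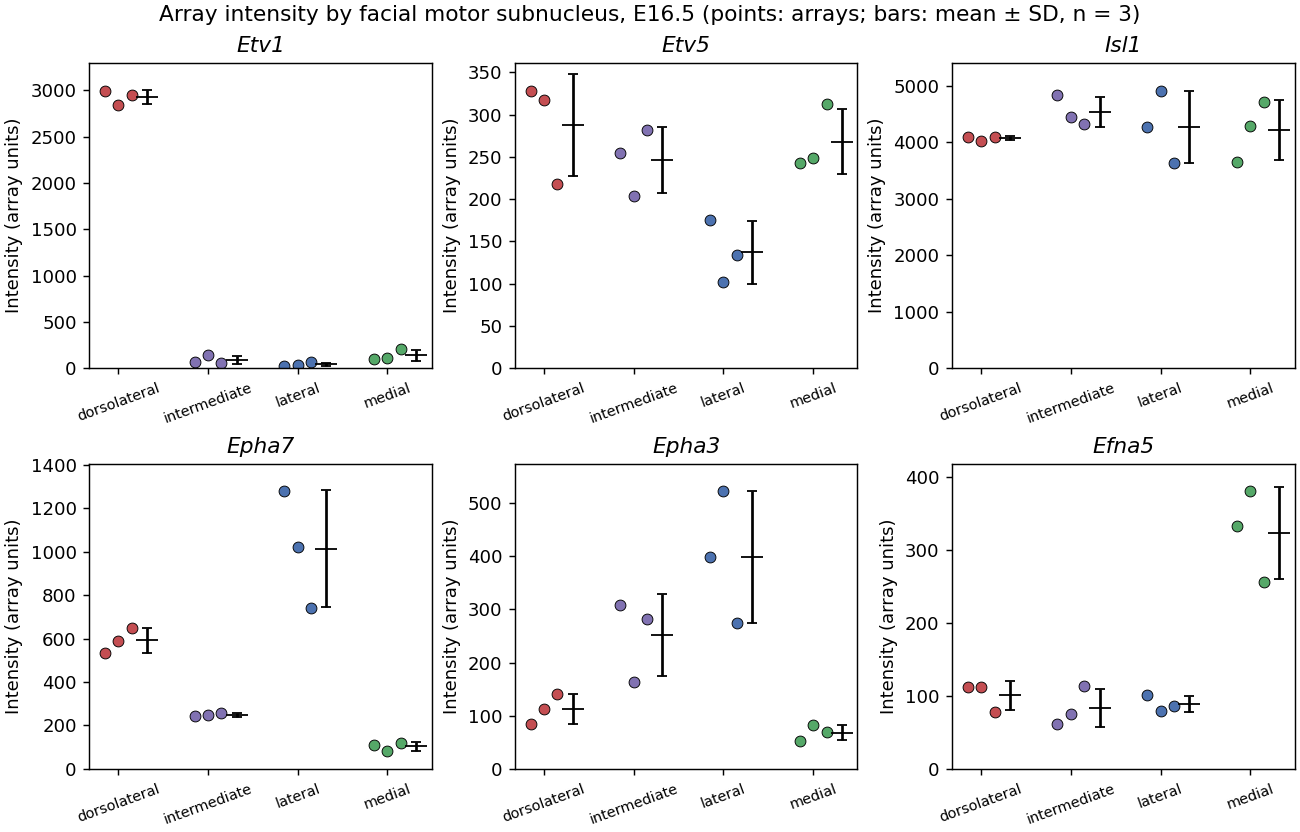
Intensity (vertical axes, array units from 0) of 6 genes in the 4 subnuclei, with points for single arrays and bars for the mean ± SD (n = 3). Etv1 is near 2929 in dorsolateral tissue and under 210 on every other array, Isl1 is level across subnuclei, Epha7 is highest in lateral and lowest in medial tissue, and Efna5 is highest in medial tissue.

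In the dorsolateral subnucleus 230 genes were higher and 208 lower than in the others. After Etv1 the largest rise was in sclerostin domain containing 1 (Sostdc1), a secreted antagonist of BMP and Wnt signals, at 1767 ± 473 against 44.8 to 68.0 elsewhere (26.2-fold, adjusted p = 5.29e-05). Amphiregulin, a ligand of the EGF receptor, rose 5.93-fold to 743 ± 113. The G protein subunit gamma 8 (Gng8) rose 5.68-fold to 311 ± 70.9, and the adhesion molecule Cntn3 rose 5.36-fold to 596 ± 174. Gria3, a subunit of AMPA glutamate receptors, was at 967 ± 112 in dorsolateral and 741 ± 119 in medial tissue, against 159 ± 39.5 in intermediate and 63.3 ± 34.8 in lateral tissue. Penk, the enkephalin precursor, was at 989 ± 177 against 99.7 ± 23.4 in medial tissue (4.48-fold over the others, adjusted p = 0.0296). The rest of the 10 largest rises were steroid 5 alpha-reductase 2-like 2 (4.04-fold) and the transcription factors Ebf3 (3.78-fold) and Sp6 (3.78-fold), of which Sp6 was as bright in intermediate tissue (172 ± 167).

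The largest fall in the dorsolateral subnucleus was in Sv2b, a synaptic vesicle glycoprotein, at 207 ± 99.5 against 1249 to 1563 elsewhere (log2 difference -2.66, adjusted p = 0.000791). Prostaglandin D2 synthase (Ptgds), at 22.7 ± 12.7, and the interleukin 17 receptor, at 127 ± 33.7, were next. The orphan nuclear receptor Nr4a3 was at 135 ± 33.4. The neuropeptide Vip was at 46.1 ± 0.693 against 424 ± 169 in intermediate tissue. The cGMP-dependent protein kinase II (log2 difference -1.80), the adhesion genes Pcdh20 (-1.77) and contactin associated protein 4 (-1.64), and the orexin receptor 1 (-1.58) were also among the largest falls.

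Among the fixed groups, 4 of 14 measured markers of alpha and gamma motor neurons were lower in dorsolateral tissue and none was higher: Sv2b, the GDNF co-receptor Gfra1 (log2 difference -0.80), Chodl (-0.56) and Esrrg (-0.70). Adjusted over the list alone, 2 were higher and 4 lower. The 20 measured neuropeptide genes split evenly, with 4 higher, including Npy (1.68) and Cbln1 (1.32), and 4 lower, including Cbln2 (-1.40). Of 49 neurotransmitter receptors 3 were higher, namely the adrenergic receptor Adra2a (1.88), the substance P receptor Tacr1 (1.68) and Gria3 (2.21), and 5 were lower. Of 28 semaphorin, plexin and neuropilin genes 3 were higher, including Sema5a (1.14), and 2 lower, Nrp1 (-1.23) and Sema3a (-0.94). Of 7 inhibitory neuron markers Gad1 was higher (1.05, adjusted p = 0.0401), and 2 were higher when adjusted over the list alone. Epha7 was higher (0.94, adjusted p = 0.0091) and Epha4 lower (-0.92, adjusted p = 0.0227). Of the 30 lists, camera with a preset correlation placed oxidative phosphorylation (42 genes, median log2 difference -0.13, adjusted p = 0.000985) and endothelium and pericytes (15 genes, -0.27, adjusted p = 0.0145) below other genes, although no member of either passed alone. Both calls were lost, each at an adjusted p = 0.875 with an estimated correlation. The count of 438 genes fell to 250, 170 and 168 without dorsolateral replicates 1, 2 and 3, and to 290 with a pseudocount of 1. The balance of 230 higher and 208 lower turned to 207 and 267 after quantile normalization, 200 and 237 after median centring, and 180 and 233 with the stricter filter.

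In the intermediate subnucleus 214 genes were higher and 147 lower than in the others. Pancreatitis-associated protein, a secreted C-type lectin, was at 1252 ± 640 against 7.43 to 91.2 elsewhere (21.9-fold, adjusted p = 0.000169). Gastrin releasing peptide (Grp) was at 1245 ± 572 against 25.5 to 110 elsewhere (16.3-fold, adjusted p = 8.99e-06). The zinc finger factor Gata6 was at 320 ± 43.7 (7.51-fold), hepatocyte growth factor (Hgf), the ligand of Met, at 210 ± 79.8 (6.78-fold), and neurexophilin 3 at 215 ± 30.3 (5.73-fold). Pro-opiomelanocortin (Pomc), the precursor of corticotropin and beta-endorphin, was at 560 ± 145 (5.62-fold) and the guidance gene Sema5b at 1274 ± 417 (5.50-fold). Carbonic anhydrase 3 (5.42-fold), the cGMP-dependent protein kinase II (5.34-fold) and the dynorphin precursor Pdyn (5.06-fold) followed.

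The largest fall in the intermediate subnucleus was in fidgetin, an AAA ATPase that severs microtubules, at 64.7 ± 30.3 against 330 to 1717 elsewhere (log2 difference -3.03, adjusted p = 4.29e-05). Npy was at 13 ± 2.12 (-2.80), close to its medial level of 22.2 ± 4.21. The teneurins Tenm2 (313 ± 60.4) and Tenm3 (246 ± 39), transmembrane adhesion proteins, were also lower, as were the transcription factor Maf (357 ± 58.4) and the semaphorin receptor Nrp2 (1076 ± 379 against 2488 to 4732 elsewhere). The neuropeptide neurotensin (Nts) was at 261 ± 120 and the thyrotropin-releasing hormone degrading enzyme at 66.7 ± 22.8. Sostdc1 and Etv1 completed the 10, with dorsolateral tissue as the high group.

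Of the 20 neuropeptide genes 7 were higher in intermediate tissue, including Grp and galanin (Gal, 1012 ± 193), and 4 lower, including Npy and Nts. Adjusted over the list alone, 10 were higher and 5 lower. Camera did not place this list apart (adjusted p = 0.0824). Motor neuron transcription factors went both ways: Foxp1 (log2 difference 1.67) and Phox2a (1.37) were higher, and Tbx20 (-0.80) and Nr2f2 (-0.95) were among 5 of 30 that were lower. Of 31 Wnt and BMP ligands and modulators 4 were higher, including the BMP antagonist Grem1 (2.18) and Wnt4 (1.34), and 2 lower, Fzd1 (-1.01) and Fstl5 (-1.44). Of 32 genes in the list of immunoglobulin-family adhesion genes, which also holds the teneurins, 2 were higher and 5 lower, among them Dcc (-0.92) and Ntm (-0.90). Of 7 inhibitory neuron markers Gad1, which makes GABA, was lower (-1.44). Of 16 retinoic acid pathway genes 2 were higher, the binding protein Crabp2 (log2 difference 0.89) and the synthesizing enzyme Aldh1a3 (540 ± 103, adjusted p = 0.00687), and 1 lower, the synthesizing enzyme Aldh1a2 (-0.99).

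Camera with a preset correlation placed 9 of 30 lists apart in intermediate tissue. Above other genes were Wnt and BMP genes, FGF and ERK response genes, and endothelium and pericytes (each at an adjusted p of 0.0214), classical cadherins (0.0248), trophic factor receptors (0.0344) and ribosomal proteins (0.0344). Below were immunoglobulin-family adhesion genes and inhibitory neuron markers (each 0.0214) and non-clustered protocadherins (0.0344). None held with an estimated correlation. In that order the adjusted p with an estimated correlation was 0.195, 0.393, 0.376, 0.195, 0.327 and 0.709 for the lists above other genes, and 0.376, 0.195 and 0.376 for those below. Among 15 endothelial genes the member that passed alone was Abcb1a (1.05), a transporter of the blood-brain barrier, of whose 2 kept probe sets 1 was higher, and no ribosomal protein, trophic factor receptor or FGF response gene passed alone. The count of 361 genes fell to 174 and 199 without intermediate replicates 1 and 3.

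In the lateral subnucleus 483 genes were higher and 615 lower than in the others. Npy was at 730 ± 253 against 283 ± 42.6 in dorsolateral and under 23 in intermediate and medial tissue on average (10.4-fold over the others, adjusted p = 1.24e-06). Fidgetin was at 1717 ± 244 (7.70-fold) and the interleukin 17 receptor at 1641 ± 365 (adjusted p = 2.49e-05). The angiotensin II receptor type 2 rose to 222 ± 59.7 (6.26-fold) and the angiotensin receptor 1b to 280 ± 90.9 (5.02-fold). The serotonin receptor Htr2c was at 293 ± 70.6 against 29.8 to 42.9 elsewhere (6.05-fold, adjusted p = 5.54e-05). Ptgds was at 482 ± 306 (5.14-fold), carboxypeptidase B1 at 356 ± 42.3 (5.02-fold), the anion transporter Slc26a7 at 181 ± 69.4 (3.82-fold) and Epha7 at 1013 ± 269 (3.77-fold).

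The largest falls in the lateral subnucleus were in pancreatitis-associated protein (7.43 ± 5.77) and Aldh1a3 (36.9 ± 37.6 against 221 to 540 elsewhere, log2 difference -2.85, adjusted p = 0.000296). Gria3 (-2.78) and cysteine-rich motor neuron 1 (Crim1, 61.8 ± 36.0 against 336 to 702 elsewhere, -2.71) followed, then Etv1. The protocadherins Pcdh8 (242 ± 203 against 801 to 2161 elsewhere) and protocadherin 21 (46.4 ± 27.8) were lower. Foxp1, a forkhead factor that sets motor neuron column identity in the spinal cord, was at 183 ± 58.9 against 670 to 1574 elsewhere (-2.38, adjusted p = 1.54e-05), with all 6 of its kept probe sets lower. Glutathione S-transferase mu 6 (1.57 ± 0.252) and the chromatin protein Hmga2 (17.7 ± 9.10) were near the floor of the arrays.

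Eph receptors split within the lateral subnucleus. Epha3 (log2 difference 1.52), Epha4 (0.75), Epha5 (1.19) and Epha7 (1.92) were among 5 of 20 Eph and ephrin genes that were higher, and Ephb1 (-1.56) among 3 that were lower. Of 30 motor neuron transcription factors 7 were lower, including Foxp1, Nkx6-1 (-1.41) and Zfhx3 (-1.66), and 3 higher, including Nr2f2 (1.54). Of 49 neurotransmitter receptors 10 were lower, including the glycine receptor subunit Glra2 (-1.51) and the kainate receptor subunit Grik1 (-1.32), and 3 higher. Of 16 FGF and ERK response genes 5 were lower, including Etv5 and Dusp6 (-1.04), and Fos was higher (0.91). Of 20 neuropeptide genes 4 were higher, including Nts (1.67) and Nmb (1.39), and 8 lower, including Pnoc (-1.63). Of 7 inhibitory neuron markers Slc32a1 (-1.34) and Slc6a5 (-0.82), the vesicular transporter of GABA and glycine and the plasma membrane glycine transporter, were lower, and 6 were lower when adjusted over the list alone. Slc32a1 was lower in 2 of its 3 kept probe sets and Slc6a5 in 1 of its 2. Of 18 genes of astrocytes and radial glia 2 were lower, Ptprz1 (-1.41) and Hes5 (-0.68).

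Camera with a preset correlation placed 5 of 30 lists apart in lateral tissue: inhibitory neuron markers (adjusted p = 0.00299), neurotransmitter receptors (0.0473) and FGF and ERK response genes (0.0473) lower, and oxidative phosphorylation (0.0357, median log2 difference 0.13) and ribosomal proteins (0.0483, median 0.09) higher. None held: in that order the adjusted p with an estimated correlation was 0.142, 0.662, 0.578, 0.712 and 0.793. No gene of the last pair of lists passed alone. The balance of higher and lower genes moved with the scaling: 44.0% of the 1098 genes were higher as deposited, 52.8% after quantile normalization, 58.4% after centring each array on its median and 52.0% with the stricter filter. The count fell to 520 and 562 without lateral replicates 2 and 3.

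In the medial subnucleus 231 genes were higher and 167 lower than in the others. Bcl11b, a zinc finger factor that marks subcerebral projection neurons in the cortex, was at 260 ± 73.3 against 6.73 to 23.3 elsewhere (9.62-fold, adjusted p = 1.17e-05). Insulin receptor substrate 4 was at 425 ± 63.4 (5.19-fold) and DEP domain containing 6 (Deptor), an inhibitor of mTOR, at 374 ± 22.8 (4.93-fold). The receptor for thyrotropin releasing hormone was at 310 ± 146 (4.54-fold). Phenylethanolamine-N-methyltransferase (Pnmt), the enzyme that makes adrenaline, was at 264 ± 110 against 26.7 to 92.8 elsewhere (4.36-fold, adjusted p = 0.00142). Rasgrf1 (601 ± 77.8), the transcription factors Dach1 (320 ± 78.3) and Klf5 (103 ± 27.1), Pcdh8 (2161 ± 519) and corticotropin releasing hormone (Crh, 128 ± 27.2) completed the 10.

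The largest falls in the medial subnucleus were in Grp (25.5 ± 10.8, log2 difference -2.46) and Npy (-2.27), the peptides that led in intermediate and lateral tissue. Epha7 was at 103 ± 20.4 (-2.20, adjusted p = 3.7e-05) and Epha3 at 68.4 ± 14.3 (-1.50, adjusted p = 0.00379), while Efna5, which binds EphA receptors, was at 323 ± 62.5 against 83.5 to 101 elsewhere (3.17-fold higher, adjusted p = 0.000412). Penk (99.7 ± 23.4, adjusted p = 0.045), tumor suppressor candidate 5 (-1.86), carbonic anhydrase 3 (-1.75) and Cyp1b1 (-1.66) were lower. So were Nov, a secreted matrix protein at 1192 ± 195 against 1563 to 6101 elsewhere, and cysteine-rich protein 1 (118 ± 21.7). Carbonic anhydrase 3 was as low in lateral tissue (39.4 ± 3.69) as in medial tissue (39.6 ± 21.8).

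Markers of inhibitory neurons were higher in medial tissue in 4 of 7 cases and in 6 when adjusted over the list alone. The 4 were Tfap2b (log2 difference 1.47), Gad2 (1.01), Slc6a5 (0.97) and Gata2 (0.93), all dim at 83.1 or less. Camera placed this list above other genes with a preset correlation (adjusted p = 8.12e-06), and it held at an adjusted p = 0.0273 with an estimated correlation, alone among the list calls of the 4 subnuclei. Slc32a1 entered the list only after a first look at the values, and without it the unadjusted camera p was 2.03e-06, or 0.00124 with an estimated correlation. Gad1 was at 148 ± 34 in dorsolateral and 146 ± 45.2 in medial tissue, and Slc32a1 at 209 ± 105 and 203 ± 57. The list of immunoglobulin-family adhesion genes, which also holds teneurins, was placed higher too (adjusted p = 0.019). Of its 32 genes 4 were higher, including the teneurin Tenm2 (1.69) and Alcam (1.02), and Ntm was lower (360 ± 32.1). The list call was lost (adjusted p = 0.73 with an estimated correlation). Ribosomal proteins were placed lower (adjusted p = 0.0396), with no member past the threshold, and that call was lost (adjusted p = 0.781 with an estimated correlation).

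Of 30 motor neuron transcription factors 5 were higher in medial tissue, including Esrrg (1.36) and Lhx4 (1.21), and 5 lower, including Tbx2 (-1.21) and Pbx3 (-0.98). Of 49 neurotransmitter receptors 7 were higher, including Glra2 (1.38) and Gria3 (1.70), and Grm5 was lower (-0.98). The protocadherins Pcdh8, Pcdh9 (0.82) and Pcdh20 (1.62) were higher among 7 measured. The count of 398 genes fell to 169, 152 and 166 without medial replicates 1, 2 and 3, and to 255 with a pseudocount of 1. It was 245 with the 3'/5' ratio of each array in the model. With the Xist level of each array as a covariate, a fit chosen after the data were seen, it fell to 149, of which 131 were among the 398. Xist was lowest on medial replicates 2 and 3, at 7.5 and 9.6, so its level overlaps with medial tissue. This fit therefore cannot tell differences tied to sex from those of the subnucleus, or either from a loss of power.

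**Figure D4:**
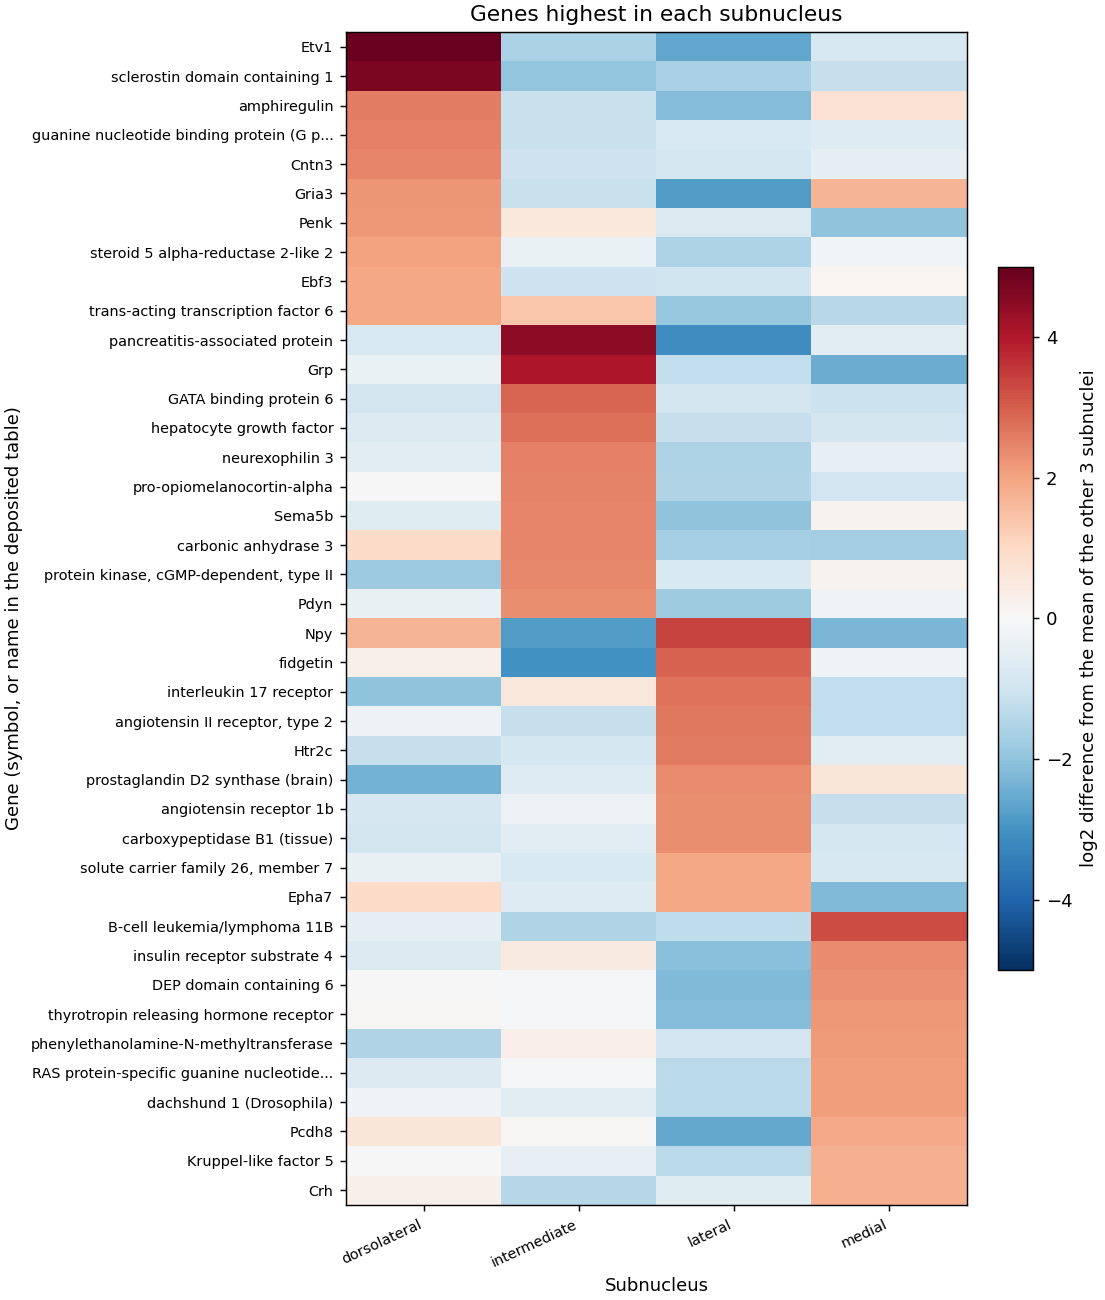
Log2 difference of each subnucleus from the mean of the other 3 (colour scale, from -5 to 5) for the 10 named genes with the largest rise in each subnucleus (rows) in all 4 subnuclei (columns). Etv1 reaches 4.95 in dorsolateral, Grp 4.03 in intermediate, Npy 3.38 in lateral and Bcl11b, listed by its full name, 3.27 in medial tissue.

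The pairwise comparisons asked which subnuclei differ most from each other. Lateral against medial tissue differed in 961 genes (443 higher and 518 lower in lateral) and dorsolateral against lateral in 903 (465 and 438). Intermediate against lateral differed in 568 (361 and 207), dorsolateral against intermediate in 487 (214 and 273), dorsolateral against medial in 294 (131 and 163) and intermediate against medial in 269 (136 and 133). Etv1 was 29.5-fold higher in dorsolateral than in intermediate, 50.1-fold higher than in lateral and 19.9-fold higher than in medial tissue, and Sostdc1 32.3, 26.7 and 20.9-fold higher. Npy was 24.8-fold lower in intermediate than in lateral tissue and 18.9-fold higher in lateral than in medial tissue. Grp was 29.2-fold higher in intermediate than in medial tissue and 15.2-fold higher than in lateral tissue. Bcl11b was 7.03-fold lower in dorsolateral, 12-fold lower in intermediate and 10.6-fold lower in lateral than in medial tissue. Epha7 was higher in lateral than in medial tissue (log2 difference 3.09, adjusted p = 1.02e-05), and Gria3 13.4-fold higher in dorsolateral than in lateral tissue (3.62e-05).

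Other genes with the largest pairwise differences were pancreatitis-associated protein, 51.2-fold higher in intermediate than in lateral tissue, and Aldh1a3, 12.5-fold higher there. Fidgetin was 22.3-fold and the angiotensin type 2 receptor 7.15-fold lower in intermediate than in lateral tissue. Between dorsolateral and lateral tissue the interleukin 17 receptor was 11.7-fold, Ptgds 11.6-fold and Htr2c 7.05-fold lower in dorsolateral. Between dorsolateral and medial tissue Penk was 8.71-fold higher, and Pnmt 6.55-fold and Sv2b 6.31-fold lower, in dorsolateral. Tenm2 was 6.20-fold and Crh 5.20-fold lower, and carbonic anhydrase 3 8.81-fold higher, in intermediate than in medial tissue. Deptor was 10.3-fold lower in lateral than in medial tissue.

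Pairwise counts depended on single arrays and on settings. The 487 genes fell to 266, 272, 303 and 284 without dorsolateral replicates 2 and 3 and intermediate replicates 1 and 3. The 903 fell to 588, 456, 473, 541 and 502 without dorsolateral replicates 1, 2 and 3 and lateral replicates 2 and 3. The 294 fell to 147, 178 and 183 without dorsolateral replicate 2 and medial replicates 1 and 3, and the 269 to 152, 154, 171, 118 and 131 without intermediate replicates 1 and 3 and medial replicates 1, 2 and 3. The 961 fell to 543, 608, 518, 503 and 563 without lateral replicates 2 and 3 and medial replicates 1, 2 and 3. Of the 903 genes 51.5% were higher in dorsolateral as deposited, 41.2% after quantile normalization, 37.1% after median centring and 44.0% with the stricter filter. Of the 961 genes 46.1% were higher in lateral as deposited, 53.0% after quantile normalization, 58.8% after median centring and 51.4% with the stricter filter. With array weights the 294 became 468, with a pseudocount of 1 the 269 became 158, and with the Xist covariate, chosen after the data were seen, the 294 became 192 and the 269 became 70. On the 6 arrays of the pair alone the 903 became 503, the 568 became 344 and the 961 became 572.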

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

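The fit of probe sets without a gene name, and the choice of those printed, were made after the data were seen. Probe sets without a gene name lie outside the comparisons of named genes, and 4894 of them passed the filter. Fitted with limma in the same way and adjusted among themselves, 89 differed in dorsolateral tissue against the others (68 higher, 21 lower), 66 in intermediate (32 higher, 34 lower), 189 in lateral (49 higher, 140 lower) and 67 in medial tissue (46 higher, 21 lower). They were singled out because they carry signal in data that no comparison of named genes used.

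Those of largest rise were chosen after their values were seen. In dorsolateral tissue 1 was at 1954 ± 38 against 71.2 ± 15.1, 39.9 ± 17.6 and 76.8 ± 5.44 in intermediate, lateral and medial tissue (n = 3 each, limma adjusted p = 6.17e-09). Another was at 837 ± 150 there and at a mean of 38.6 or less elsewhere. Both were high in dorsolateral tissue alone, as Etv1 was, and whether they read Etv1 or another named gene was not tested. In medial tissue 1 was at 1193 ± 194 against 30.6 to 122 elsewhere (17.4-fold), and in lateral tissue 1 was at 647 ± 133 against 19.2 to 130 (7.49-fold). In intermediate tissue the largest rise was 3.9-fold, to 205 ± 80.5. Whether the probe sets of medial, lateral and intermediate tissue read a named gene was not tested either.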

How the results depend on the processing

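The Xist covariate was chosen after the data were seen, and the other alternatives before the data were examined. No recomputed gene or list result changed direction past the threshold under any alternative, and the comparison of deposited tables was not run because both hold equal values. Only the 390 gene results named by rule were recomputed. Apart from the always-named genes they were chosen for passing the threshold, so their stability does not stand for all calls. Without dorsolateral replicate 3, for example, 161 of the 438 dorsolateral genes were still called. Of 8604 recomputed gene values 7713 kept their direction and side of the threshold, 813 lost the call, 34 gained it, and 44 that passed in neither fit changed sign. Of 434 list values 95 lost the call. Over all counts of genes, filters, quantile normalization, median centring and the mean of probe sets left every count within 1.5 times. With log2(value + 1) there were 290 genes in dorsolateral against the others, 255 in medial against the others and 158 between intermediate and medial. Trend and robust settings raised the F test count to 1926, and array weights raised dorsolateral against medial to 468. With the Xist covariate, medial against the others gave 149, dorsolateral against medial 192 and intermediate against medial 70. Fits on 6 arrays gave 503 for dorsolateral against lateral, 344 for intermediate against lateral and 572 for lateral against medial. Where fewer arrays entered a fit, fewer degrees of freedom remained; otherwise the cause was not tested.

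Leaving out 1 array gave 929 to 1201 genes by the F test. It gave 168 to 413 genes in dorsolateral, 174 to 412 in intermediate, 520 to 1018 in lateral and 152 to 375 in medial tissue against the others. Pairs gave 266 to 547 for dorsolateral against intermediate, 456 to 894 for dorsolateral against lateral, 147 to 332 for dorsolateral against medial, 382 to 541 for intermediate against lateral, 118 to 290 for intermediate against medial and 503 to 947 for lateral against medial. Etv1 ranged from 4.89 to 5.06 in dorsolateral, from -1.90 to -1.39 in intermediate (adjusted p 0.0037 to 0.0527), from -2.81 to -2.40 in lateral and from -1.10 to -0.62 in medial tissue. 

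Counts of shifted lists were unstable. The 2 lists of dorsolateral tissue became 4 with no filter, 1 with the stricter filter, 0 with an estimated correlation and 0 to 3 without 1 array. The 9 of intermediate tissue became 0 with an estimated correlation and 4 to 12 without 1 array. The 5 of lateral tissue became 3 with the stricter filter, 9 with median centring, 8 with trend and robust settings, 2 with the Xist covariate, 0 with an estimated correlation and 1 to 9 without 1 array. The 3 of medial tissue became 1 with an estimated correlation and 1 to 3 without 1 array.

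The replicate number as a block gave 1132 genes by the F test, 374, 320, 919 and 305 in dorsolateral, intermediate, lateral and medial tissue, and changed no call of Etv1. Deviations of 18 same-numbered pairs correlated at -0.124 to 0.163, with 3 pairs over 0.1, and 6 of 12 arrays correlated best with their own number. These correlations give no clear sign of pairs, but with so few arrays they cannot exclude them. Xist on the arrays numbered 2 was 191.5, 1657, 1586 and 7.5 in dorsolateral, intermediate, lateral and medial tissue. This argues against the same embryos in all of them. The intermediate and lateral values are close, and the deviations of that pair correlated at 0.153, so shared embryos stay open for it. On the arrays numbered 3 Xist was 1461, 1048, 97.1 and 9.6 in that order, which leaves dorsolateral and intermediate tissue open. On the arrays numbered 1 it was 2130, 2398, 1391 and 1724 in that order, so shared embryos stay open for these.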

Other observations

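The tests of the inhibitory neuron markers, that of the lateral lead with each subnucleus short of 1 of its own arrays, and that of the estimated correlation for oxidative phosphorylation and ribosomal protein genes, were chosen after the results were seen. Voltage-gated potassium channel genes, which set the firing of neurons, differed between subnuclei in both directions. Of 29 measured, 3 were higher in dorsolateral tissue, including Kcna5 (log2 difference 1.54, limma adjusted p = 0.000957) and Kcna6 (1.00), and Kcnip1 was lower (-1.14, in 2 of its 3 kept probe sets). In lateral tissue 5 were lower, including Kcnab1 (-1.36), Kcna5 (-0.96) and Kcnc4, which was at 477 ± 220 against 2031 ± 197 in medial tissue, and Kcnip4 was higher (0.93). In intermediate tissue Kcnab1 was higher (1.04) and Kcnip4 lower (-1.31). In medial tissue 3 were higher, including Kcnc4 (1.41) and Kcna2 (0.68), and Kcna6 was lower (-0.72). Genes of the retinoic acid pathway were lower in lateral tissue in 3 of 16 cases, Aldh1a3, the degrading enzyme Cyp26b1 (-1.26) and the binding protein Crabp1 (-1.71), and higher in medial tissue for Aldh1a2 (1.31) and Crabp1 (1.43). Camera placed neither list apart in these subnuclei (adjusted p = 0.0607 for each in lateral tissue, 0.279 and 0.427 in medial tissue), nor the potassium channels in dorsolateral (0.862) or intermediate tissue (0.552).

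Among the motor neuron transcription factors, Tbx3 was at 721 ± 93.8 in lateral tissue against 240 ± 11.9 in medial tissue, Tbx2 at 175 ± 24.8 in medial tissue against 368 to 471 elsewhere, and Tbx20 at 1161 ± 78.3 in intermediate tissue against 1872 to 2169 elsewhere. Phox2a was at 287 ± 59.1 in intermediate and 241 ± 34.7 in medial tissue, against 70.9 ± 26.5 in dorsolateral and 55.7 ± 6.39 in lateral tissue. Of the lists of other cell types, genes of dividing cells, erythroid cells, oligodendrocyte lineage, and microglia and macrophages had at most 1 member past the threshold in any subnucleus.

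The splits argue against chance for a difference among the subnuclei as a whole, by the F test. For the count of a single subnucleus they cannot decide. There the remaining arrays were regrouped too, which put real differences into the spread between arrays and favoured the real split. The real split gave the most genes of 100 splits (1 of 100 in each of 5 tests): 1263 against at most 415 by the F test, 438 against 377 in dorsolateral, 361 against 2 in intermediate, 1098 against 115 in lateral and 398 against 63 in medial tissue. The highest other split for dorsolateral tissue was the trio of lateral arrays, and for lateral and medial tissue the trio of dorsolateral arrays, which are real groups. The next highest gave 22, 6 and 3 genes. For the pairs, 10 splits are too few for a share under 0.05: the real split was the 1 of 10 with the most genes in each of the 6, with 487, 903, 294, 568, 269 and 961 genes against at most 1 in any other split (1 for intermediate against lateral and 0 in the others). For the counts of shifted lists, as many lists came from 58 of 100 splits for dorsolateral, 16 for lateral and 39 for medial tissue, so chance cannot be excluded there, with up to 13 lists in another split. For intermediate tissue 2 of 100 splits gave 9 or more, with 12 as the highest other.

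The lateral subnucleus had the most genes apart, 1098 against at most 438. With the 3'/5' ratio of each array in the model 856 genes were called in lateral tissue, against at most 413 in another subnucleus. After quantile normalization there were 1078, of which 952 were among the 1098, against at most 474. These counts argue against RNA quality as that ratio measures it, or the authors' scaling, as the whole cause of the lead. Without lateral replicate 2 there were 520 genes, of which 479 were among the 1098, against at most 408 in another subnucleus. This count lay between the bounds set beforehand, but every subnucleus had fewer genes without 1 of its own arrays. Without 1 of their own arrays the others had at most 277 genes called, and lateral tissue at least 520, which argues against a single lateral array as the whole cause. A difference of the lateral motor neurons stays a hypothesis found on the same data.

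Of 7 inhibitory neuron markers 4 were higher in medial tissue, and 2 were lower in lateral tissue, where the list call was lost (adjusted p = 0.142 with an estimated correlation); in dorsolateral tissue Slc32a1 was at 209 against 203 in medial tissue. A candidate explanation is that local inhibitory neurons were captured with the motor neurons. Leaving out Slc32a1, the most changed of 7, 5 of the other 6 were higher in medial than in lateral tissue, which restates the pattern and cannot tell captured inhibitory neurons from expression by medial motor neurons, so both stay open. A lower share of motor neurons in the medial captures would raise other cell types alike only if all of them took the place of motor neurons. Of 4 non-neuronal lists 2 had a median at or below 0, which decides nothing. Their highest upper quartile was 0.261, below the lower quartile of 0.909 of the inhibitory markers. The non-neuronal lists thus did not share the rise of the inhibitory markers. The inhibitory list was picked for that rise and the comparison was chosen afterwards, so it restates the pattern and cannot decide about an even replacement. Motor neurons replaced by inhibitory neurons alone would not show in these lists.

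Oxidative phosphorylation and ribosomal protein genes were slightly higher in lateral tissue, with a median log2 difference of 0.111 over 90 genes. With the 3'/5' ratio in the model the median was 0.0502 (quartiles -0.0485 and 0.158), just under the bound of 50% set for RNA quality as the cause, and by less than the quartiles spread. With the correlation estimated from the arrays the smaller camera adjusted p of both lists was 0.712. Arrays that vary in these genes together would give that, but so would genes regulated together. Of 19 list calls 18 were lost in this way, so the value does not bear on a technical source. The median with the 3'/5' ratio leaves such a source open, and a biological difference between subnuclei stays untested.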
